A study of Mus musculus with 10 samples.

How the data were processed

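RNA was measured by sequencing in 10 libraries of cells sorted from the spinal cord of mice that carry GFP under Lfng or under Aldh1l1 control. Per the labels' protocols, dissociated cells were sorted by fluorescence into lysis buffer, RNA was purified on micro-scale columns, and libraries were made from 10 ng of total RNA with the NuGEN Trio RNA-Seq kit. The labels place the libraries in 4 groups by reporter and GFP status, with 3 libraries in each Lfng-GFP group and 2 in each Aldh1l1-GFP group. Replicate numbers follow the order of the records and pair no libraries. No label gives an animal, a batch or a sorting day, so the p-values measure the spread between these libraries, which may be technical.

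The authors deposited a table of raw counts per gene symbol and a table of variance-stabilized values on the log2 scale. The submitters' processing notes name FastQC, MultiQC, STAR 2.5.0a, DESeq2 1.20.0 and the mm10 build. The counting program, its strand setting and the gene annotation are not given in the sources used here. Reads from overlapping, antisense or near-identical genes therefore cannot be told apart, which matters most for ribosomal protein genes and their pseudogenes, and for Hspa1a and Hspa1b. The deposited log2 values were checked against the counts divided by median-ratio size factors and were a steadily rising function of them, so only the counts were tested.

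The count table held 24421 symbols, of which 13060 passed edgeR's expression filter for the 4 groups. Of the tested symbols, 12602 (96.5%) were found in GENCODE M21, which uses the same mouse assembly as mm10 and supplied coordinates and transcript lengths. Counts per library ran from 671033 to 6210400, and a floor of 3 counts corresponded to between 0.537 and 5.05 CPM, which is counts scaled to a common library total. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. CPM values also carry TMM factors and are given as mean ± SD.

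Differences were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with all 10 libraries in 1 fit of the 4 group means. P-values were adjusted by the Benjamini-Hochberg method over the tested genes and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and the F statistic. The comparisons were GFP-positive against GFP-negative cells of each line, the 2 GFP-positive groups, the 2 GFP-negative groups, and the difference between the enrichments of the 2 sorts. Gene lists were tested with camera of limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Of 28 lists fixed beforehand, 26 had at least 3 tested members. The erythroid and mitochondrially encoded lists had too few. Lists can share members, so their tests are not independent of each other. No list call of any comparison held with an estimated correlation. The median, mean and test of a list differed in sign only in lists that were not called.

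The comparisons, the lists and the rule for naming genes were chosen before the data were examined. Named genes are Lfng and Aldh1l1, and the 10 largest rises and falls of a comparison (5 for the GFP-negative groups and the difference). Those had to be called, have a mean log2 CPM of at least 3, show no overlap between the libraries of the groups, and carry no provisional symbol. The rule also takes up to 4 members of each list with the smallest p, or the most abundant members of an unchanged list, and called members of the patterning and Hox lists. Where a group had no count, a fold is a lower bound against 3 counts over the group. With 1 to 3 counts in the lower group, the ratio of pooled counts is given with its exact binomial 95% interval.

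The pipeline was tested on simulated counts with 200 changed genes and a small planted list raised 2-fold, in place of the real effects. In the Lfng sort it recovered 7.14%, 36.1% and 68.3% of genes changed 2-fold, 4-fold and 8-fold. In the Aldh1l1 sort these shares were 0%, 11.3% and 41.7%, and between the GFP-positive groups they were 0%, 23.0% and 56.8%. The simulations made 73, 33 and 57 calls in these comparisons, against 869, 1243 and 134 in the data. With fewer changed genes the adjusted threshold is stricter, so these shares do not give the power of the real comparisons. They cover single genes and not the planted list. Genes were drawn independently of each other, so the simulation could not test the correlation preset for the lists. Alternatives were DESeq2 1.42.0, RLE in place of TMM, no filter on low counts, the libraries of the compared groups alone, an estimated correlation for the lists, and leaving out each library in turn. Removal of the ribosomal RNA gene Rn45s and thinning of all libraries to the smallest total were added after the data were seen.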

Results

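The libraries covered cells of the adult mouse spinal cord sorted by 2 reporters. Lfng encodes a glycosyltransferase that modifies Notch receptors, and Aldh1l1 encodes a folate enzyme used as a general astrocyte marker. Each sort gave a GFP-positive and a GFP-negative fraction. Counts per library were 5617749, 1245789 and 2179979 for Lfng-GFP positive cells and 3321145, 6210400 and 3982672 for Lfng-GFP negative cells. They were 3547695 and 2436550 for Aldh1l1-GFP positive cells and 671033 and 2272413 for Aldh1l1-GFP negative cells. The ribosomal RNA gene Rn45s took between 4.07% and 35.6% of the counts. These lowest and highest shares lay in replicates 1 and 2 of the Aldh1l1-GFP positive group. Correlations of log CPM within a group, computed across genes, were 0.95 to 0.98 in Lfng-GFP negative, 0.80 to 0.85 in Lfng-GFP positive, 0.83 in Aldh1l1-GFP negative and 0.72 in Aldh1l1-GFP positive libraries. No pair within a group differed by as little as sampling noise. Libraries did not always correlate most with their own group. Replicate 1 of the Lfng-GFP positive group correlated at 0.889, 0.910 and 0.908 with the Lfng-GFP negative libraries, and at 0.832 and 0.846 with its own group. Replicate 1 of the Aldh1l1-GFP positive group correlated at 0.801 with replicate 1 of the Lfng-GFP positive group, and at 0.722 with its own replicate.

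The reporters' own genes were examined first. Lfng lies on chromosome 5 from 140607320 to 140615545 and Aldh1l1 on chromosome 6 from 90486427 to 90600203 (GRCm38), both on the plus strand. Lfng was at 89.5 ± 26 CPM in Lfng-GFP positive cells (SD, n = 3) and 6.92 ± 2.3 CPM in Lfng-GFP negative cells (SD, n = 3). The log2 fold change was 3.70 ± 0.64 (SE, adjusted p = 0.00563). Aldh1l1 was also higher in Lfng-GFP positive cells, by 2.53 ± 0.54 on the log2 scale (SE, adjusted p = 0.014), a call lost in 4 of 10 fits with a library left out. In the Aldh1l1 sort, Aldh1l1 did not pass the test, with a log2 fold change of 1.57 ± 0.67 (SE, adjusted p = 0.151). Its CPM was 13.4 and 41.9 in the 2 positive libraries and 5.05 and 12.05 in the 2 negative libraries. Replicate 1 of the Aldh1l1-GFP positive group thus lay close to the higher negative library. Without that replicate the log2 fold change of Aldh1l1 was 2.15 and passed the threshold, in a fit where the lone positive library is assumed to vary like the other groups, so why Aldh1l1 did not pass with all libraries is not settled.

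**Figure D1:**
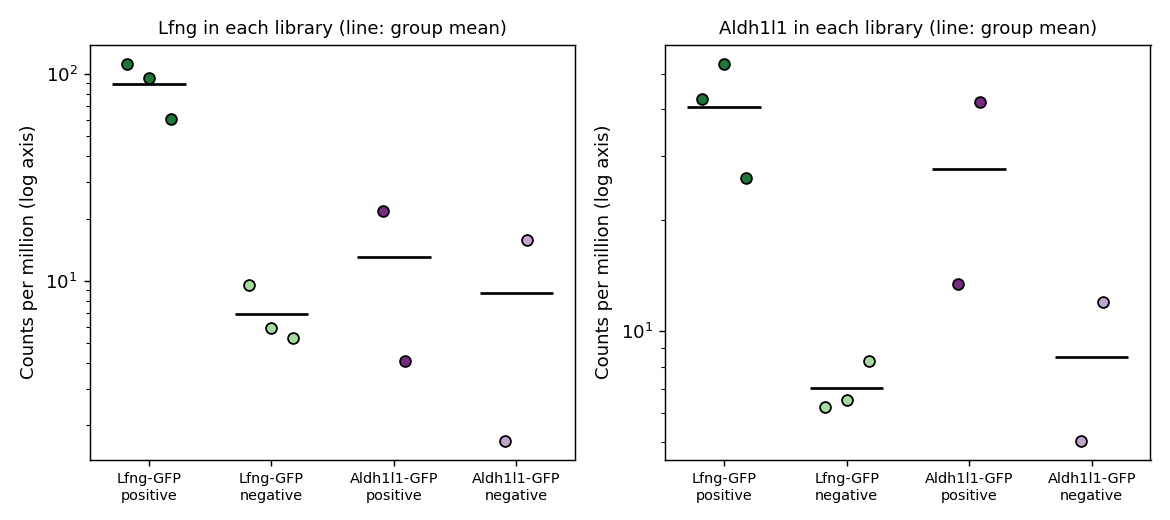
CPM of Lfng (left) and Aldh1l1 (right) on log axes, 1 point per library and a line at each group's mean. Lfng separated the Lfng-GFP fractions, whereas the Aldh1l1-GFP positive libraries lay apart at 13.4 and 41.9 CPM of Aldh1l1.

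The Lfng sort asked which genes distinguish Lfng-GFP positive cells from GFP-negative cells. Astrocyte genes were higher in the positive fraction, and myelin and ribosomal protein genes were lower. Gpr37l1, an astrocyte receptor, rose from 17.0 ± 2.5 to 228 ± 46 CPM (SD, n = 3 each), a log2 fold change of 3.75 ± 0.41 (SE, adjusted p = 0.000999). The amino acid transporter gene Slc7a10 rose by 3.94 ± 0.50 (SE, adjusted p = 0.00148). In all, 330 genes were higher and 539 lower among 13060 tested. The count of higher genes ran from 57 to 636 when single libraries were left out, and was lowest without replicate 2 of the Lfng-GFP negative group. The count of lower genes ran from 187 to 825.

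Of 16 astrocyte genes, 15 rose and 1 was not called (camera adjusted p = 4.37e-25, and adjusted p = 0.135 with an estimated correlation). Adjusted over the list alone, 15 passed. Fgfr3, a fibroblast growth factor receptor, rose by 3.07 ± 0.37, the GABA transporter gene Slc6a11 by 3.36 ± 0.43 and the connexin gene Gjb6 by 3.35 ± 0.44 (SE, adjusted p up to 0.0016). In the gray-matter astrocyte list 7 of 12 genes rose (camera adjusted p = 1.23e-08, and adjusted p = 0.135 with an estimated correlation), among them Cldn10, by 3.32 ± 0.48, and Gpc5, by 2.58 ± 0.48. The white-matter list was not called (camera adjusted p = 0.705), and its member Cryab fell by 1.43 ± 0.39 on the log2 scale (SE, adjusted p = 0.0416), a call lost in 7 of the 10 fits with a library left out. Gpc5 lost its call in 1 of them.

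Genes of ion, transmitter and synapse handling followed. Their lists need not be separate from the astrocyte lists. The summed CPM of the gray-matter list was 11100, 7367 and 10580 in the Lfng-GFP positive libraries. That of the neurotransmitter list was 10320, 6906 and 10350, so the same abundant genes may carry both. In the potassium, water and gap junction list 9 of 14 genes rose and 1 fell (camera adjusted p = 1.47e-09, and adjusted p = 0.159 with an estimated correlation). Gja1 rose by 2.62 ± 0.36, and the sodium pump gene Atp1b2 by 2.81 ± 0.49. Of 21 neurotransmitter uptake and receptor genes, 8 rose (camera adjusted p = 5.22e-11, and adjusted p = 0.159 with an estimated correlation). Of 17 synapse-organizing genes, 7 rose (camera adjusted p = 6.69e-07, and adjusted p = 0.135 with an estimated correlation), including the proteoglycan gene Bcan, by 3.36 ± 0.44. Of 20 Notch genes, Lfng, Notch1 and Notch3 rose (camera adjusted p = 1.3e-05, and adjusted p = 0.159 with an estimated correlation), with Notch1 up by 1.80 ± 0.32. Lfng is the gene of the reporter, and Notch3 is also a member of the mural list. Of 10 Hedgehog genes, Ptch1 and Boc rose, by 1.73 ± 0.38 and 2.23 ± 0.55 (camera adjusted p = 0.00343, and adjusted p = 0.135 with an estimated correlation). Leaving out 1 library took the call from Notch3 in 5 of 10 fits and from Ptch1 and Boc in 4 each.

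Lower in Lfng-GFP positive cells were 4 of 14 mature oligodendrocyte genes (camera adjusted p = 5.49e-08, and adjusted p = 0.238 with an estimated correlation). Mbp, for myelin basic protein, fell, with a log2 fold change of -2.86 ± 0.53, as did Mobp, with -2.87 ± 0.54, and Ermn, with -2.17 ± 0.52 (SE). Among the largest falls, S100b fell by 3.05 ± 0.34, and the log2 fold changes of the ferritin gene Fth1, the chaperone gene Clgn and Cdr2 were -3.03 ± 0.47, -3.54 ± 0.42 and -2.90 ± 0.42. Ribosomal protein genes fell in 46 of 74 cases (camera adjusted p = 8.41e-40, and adjusted p = 0.159 with an estimated correlation), with Rpl21 down from 648 ± 74 to 165 ± 22 CPM (SD, n = 3 each). Of 18 immediate early and stress genes 6 rose (camera adjusted p = 8.2e-08, and adjusted p = 0.159 with an estimated correlation), with Fosb up by 1.56 ± 0.30 (SE). The reactive astrocyte list was called higher with 2 of 22 genes up, Lcn2, which is also a neutrophil granule gene, and H2-D1 (camera adjusted p = 0.00415, and adjusted p = 0.356 with an estimated correlation). H2-D1 lost its call in 7 of 10 fits with a library left out, Ermn in 4 and Fosb in 1.

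Genes of other cell types moved as well. Of 12 endothelial genes, Cdh5, Esam and Flt1 rose (camera adjusted p = 5.04e-05, and adjusted p = 0.305 with an estimated correlation). Of 10 mural genes, Notch3 rose (camera adjusted p = 0.000424, and adjusted p = 0.239 with an estimated correlation). The 4 peripheral immune genes were called as a list (camera adjusted p = 0.00662, and adjusted p = 0.305 with an estimated correlation) with no single member called. Neutrophil granule genes were among the largest rises. Lcn2 was at 93.8 ± 75 against 1.92 ± 1.6 CPM (SD, n = 3 each), and Ltf was 182-fold higher with a counting interval of 61.8 to 884. The microglia list was not called (camera adjusted p = 0.964), and its median of 0.64 lay above 0 while the test pointed down. Its summed CPM was 115.6, 226.7 and 1204 in the positive and 517, 227.3 and 269 in the negative libraries, and without replicate 3 of the Lfng-GFP positive group the list was called lower (adjusted p = 3.77e-06). No dorsal, ventral or Hox gene was called. The dorsal list lay near the threshold, with a median of 1.53 and 5 of 6 members above 0 (camera adjusted p = 0.0568, and adjusted p = 0.185 with an estimated correlation). Adjusted over the list alone, 2 passed, and the list was called higher without replicate 1 of the Lfng-GFP negative group (camera adjusted p = 0.0496). With single libraries left out, Cdh5 and Flt1 lost their calls in 7 of 10 fits, Esam and Notch3 in 5 and Ltf in 2.

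**Figure D2:**
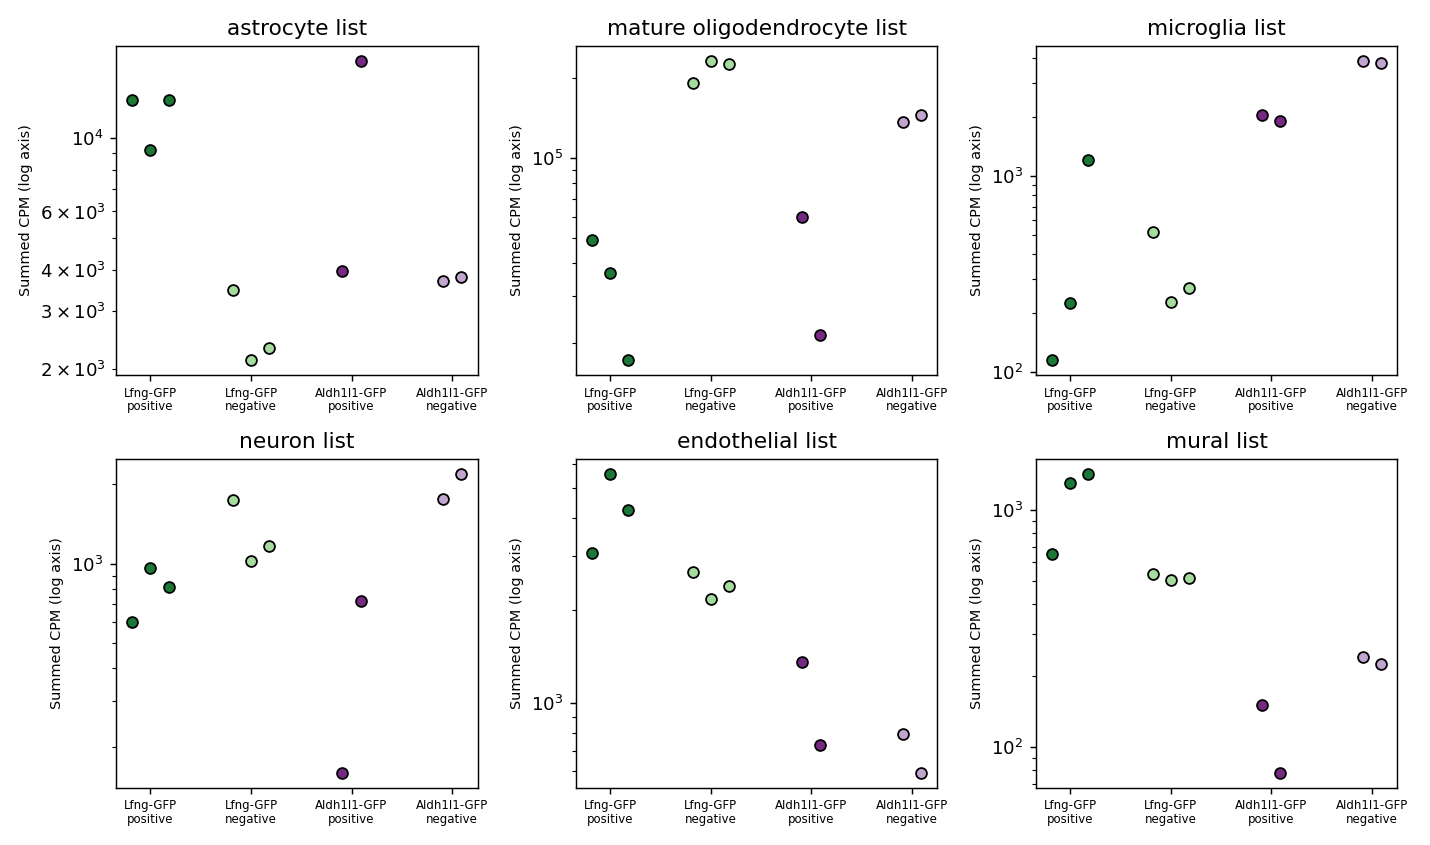
Summed CPM of the tested members of 6 cell type lists on log axes, 1 point per library. In the astrocyte panel the sum of replicate 1 of the Aldh1l1-GFP positive group, carried by its most abundant members, lay near the negative libraries, although its median log2 ratio to them over the list was 0.778 (interval 0.544 to 1.247), and all Lfng-GFP libraries lay above all Aldh1l1-GFP libraries in the mural panel.

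The Aldh1l1 sort asked the same of the general astrocyte reporter. Astrocyte, precursor and immediate early genes were higher in GFP-positive cells, and neuronal and ribosomal protein genes were lower. Slc7a10 was at 68.7 ± 42 against 1.63 ± 0.078 CPM (SD, n = 2 each), a log2 fold change of 5.38 ± 0.75 (SE, adjusted p = 0.00266). Slc6a11 rose by 3.68 ± 0.55 and Gpr37l1 by 3.31 ± 0.51 (SE, adjusted p up to 0.00301). In all, 573 genes were higher and 670 lower. With the 4 libraries of this sort alone the counts were 64 and 204, and without replicate 1 of the positive group, with its lone library assumed to vary like the other groups, they were 1174 and 1226.

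Of 16 astrocyte genes 7 rose (camera adjusted p = 1.85e-05, and adjusted p = 0.409 with an estimated correlation). The gray-matter list had 5 of 12 genes up (camera adjusted p = 0.00218, and adjusted p = 0.409 with an estimated correlation), with Cldn10 up by 4.20 ± 0.74. Its summed CPM was 3128 in replicate 1 and 12850 in replicate 2 of the positive group, against 4519 and 4737 in the negative libraries. Of 8 oligodendrocyte precursor genes, Gpr17, Cspg4 and Bmp4 rose (camera adjusted p = 0.00193, and adjusted p = 0.409 with an estimated correlation). Gpr17 was at 351 ± 330 against 13.1 ± 6.6 CPM (SD, n = 2 each). Of 14 neuron genes 6 fell (camera adjusted p = 1.13e-07, and adjusted p = 0.285 with an estimated correlation), with log2 fold changes of -3.19 ± 0.44 for Stmn2 and -3.23 ± 0.57 for the neurofilament gene Nefl. Mobp was the 1 mature oligodendrocyte gene called lower (camera adjusted p = 0.0459, and adjusted p = 0.639 with an estimated correlation). Bmp4 lost its call in 6 of 10 fits with a library left out, Gpr17, Cspg4 and Mobp in 3 and Cldn10 in 1.

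Other lists called higher were neurotransmitter uptake and receptors, with 5 of 21 genes up (camera adjusted p = 2.89e-05), synapse organization, with 5 of 17 (0.00492), potassium, water and gap junction, with 5 of 14 up and 1 down (0.00917), Notch, with 2 of 20 (0.0145), endothelial, with 1 of 12 (0.035), fibroblast, with 1 of 6 (0.0436), and Hedgehog, with Ptch1 and Boc of 10 (0.0436). The microglia list was called lower (0.0171) with no member called. Among fits with a library left out, Boc lost its call in 6 of 10 and Ptch1 in 3. Adjusted p with an estimated correlation was between 0.381 and 0.639 for these lists. In replicate 1 of the positive group the summed CPM of the neurotransmitter list was 3153, below the negative libraries at 3935 and 4118. That of the potassium, water and gap junction list was 2926, below 3114 and 3209. The sums of the other lists called higher in this paragraph lay above the negative libraries in that replicate.

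Immediate early genes rose in 12 of 18 cases (camera adjusted p = 4.02e-12, and adjusted p = 0.285 with an estimated correlation). Fosb rose by 4.27 ± 0.43 and Egr1 by 3.35 ± 0.49 (SE). Ribosomal protein genes fell in 60 of 74 cases (camera adjusted p = 2.56e-50, and adjusted p = 0.285 with an estimated correlation), and Rps28 fell by 3.10 ± 0.40. Cholesterol synthesis genes rose in 4 of 21 cases (camera adjusted p = 0.00916, and adjusted p = 0.639 with an estimated correlation), with the regulator Srebf2 up by 1.90 ± 0.40. The mural genes Vtn and Rgs5 fell, with log2 fold changes of -1.90 ± 0.46 and -1.83 ± 0.53, in a list that was not called (camera adjusted p = 0.0994). Serpina3n, a gene of reactive astrocytes, fell by 4.07 ± 0.61. Hoxd8 fell by 2.25 ± 0.66 and was the 1 Hox gene called. With single libraries left out, Rgs5 lost its call in 8 of 10 fits, Hoxd8 in 7, Vtn in 3 and Srebf2 in 2.

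Other rises of this sort were in genes without a count in the GFP-negative libraries, the shallower of which held 671033 counts. Nlrp3, an inflammasome gene, was at least 31.2-fold higher, Dgat1, for triglyceride synthesis, at least 28.4-fold and Gdpd2 at least 21.3-fold. In the other direction the neuronal gene Cntnap2 had no count in GFP-positive cells and was at least 36.3-fold lower. Rapgef4 fell from 1090 ± 110 to 57.1 ± 31 CPM (SD, n = 2 each). Slc17a6, which encodes a vesicular glutamate transporter, fell by 4.71 ± 1.09 on the log2 scale (SE, adjusted p = 0.0168). The calls of Nlrp3, Dgat1 and Slc17a6 were lost in 2 of 10 fits with a library left out and that of Gdpd2 in 1.

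The calls of the 2 sorts, which share no library, were then compared. Both called 107 genes higher and 325 lower, against 14.5 and 27.7 for independent lists of these sizes, and 0 genes in opposite directions. The shared counts ran from 29 to 251 higher and from 135 to 461 lower when single libraries were left out. They were lowest without replicate 3 of the Lfng-GFP negative group and without replicate 2 of the Aldh1l1-GFP negative group, and both were highest without replicate 1 of the Aldh1l1-GFP positive group. With the libraries of each sort alone they were 37 and 163. Shared rises included Slc7a10, Slc6a11, Gpr37l1, Cldn10 and Bcan, and the immediate early genes Fosb and Egr1. Shared falls included Mobp and many ribosomal protein genes, among them Rpl21 and Rps28. The overlap is thus not made of cell type genes alone. The difference between the sorts was tested directly. It called 0 genes with edgeR (1505 at an unadjusted p under 0.05) and 68 higher and 53 lower with DESeq2. With edgeR the counts were 80 and 109 without the filter on low counts, 189 and 122 without replicate 1 of the Aldh1l1-GFP positive group and 1 and 2 without its replicate 2, where the lone library left is assumed to vary like the other groups.

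**Figure D3:**
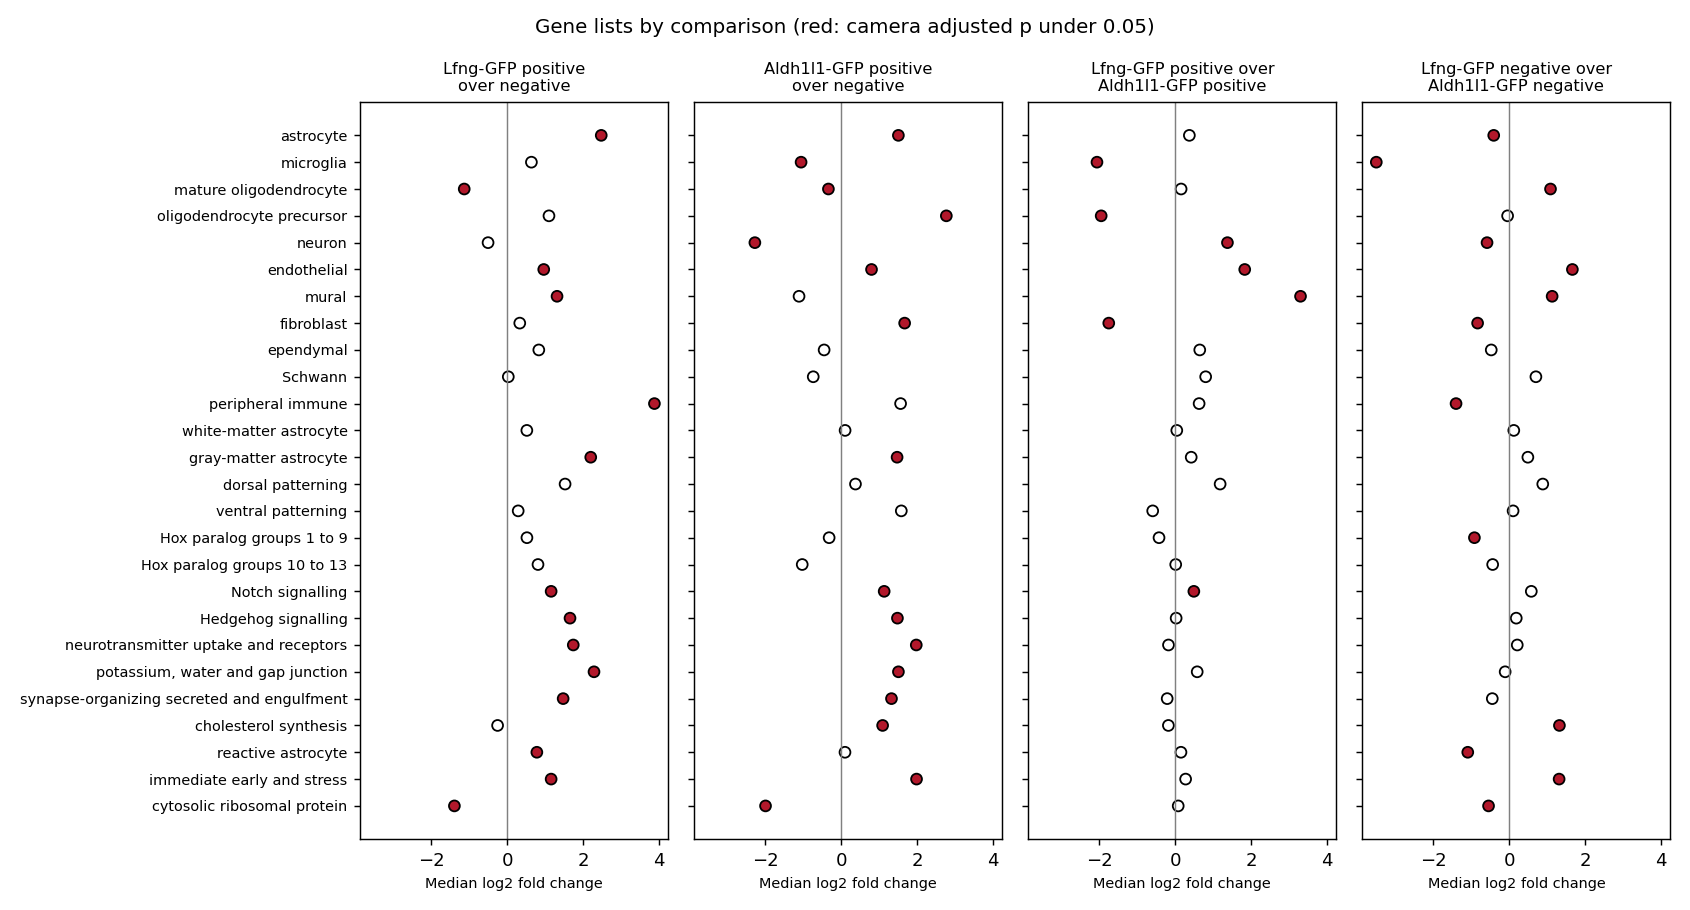
Median log2 fold change of each tested gene list in 4 comparisons, with lists past a camera adjusted p of 0.05 in red. Astrocyte genes had medians of 2.48 and 1.51 in the Lfng and Aldh1l1 sorts and of 0.38 between the GFP-positive groups. The last was not called with all libraries but was called in some fits with a library left out. With genes without a count in a group set at their bound, the median of the neurotransmitter list in the Aldh1l1 sort was 1.735 in place of 1.983, and no median of a called list otherwise changed.

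The GFP-positive groups were compared with each other. The mouse line goes with the group, and 1 of the 2 Aldh1l1-GFP positive libraries was low in Aldh1l1 itself. The mural and endothelial lists were higher in Lfng-GFP positive cells, and the microglia and fibroblast lists were lower. The pericyte gene Rgs5 was at 454 ± 140 CPM (SD, n = 3) against 27.4 ± 25 CPM (SD, n = 2), a log2 fold change of 4.01 ± 0.55 (SE, adjusted p = 0.00737). Vtn rose by 3.77 ± 0.46 and the endothelial gene Apold1 by 4.33 ± 0.56 (SE, adjusted p = 0.00581 for both). In all, 74 genes were higher and 60 lower. With the 5 libraries of these groups alone the counts were 0 and 1, and without replicate 1 of the Aldh1l1-GFP positive group they were 822 and 630, with the lone library left there assumed to vary like the other groups.

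Of 10 mural genes, Vtn, Rgs5 and Abcc9 were higher (camera adjusted p = 8.44e-15, and adjusted p = 0.117 with an estimated correlation), and 9 passed when adjusted over the list alone. Of 12 endothelial genes 6 were higher (camera adjusted p = 8.44e-15, and adjusted p = 0.17 with an estimated correlation), among them Flt1, by 1.92 ± 0.35, and Abcb1a, by 2.54 ± 0.46. Of 14 microglia genes 1 was called, Fcrls, with a log2 fold change of -4.50 ± 0.59, in a list called lower (camera adjusted p = 7.55e-12, and adjusted p = 0.289 with an estimated correlation). Of 6 fibroblast genes 2 were called, Dcn and Lum, with log2 fold changes of -4.13 ± 0.48 and -5.24 ± 0.89 (camera adjusted p = 9.62e-07, and adjusted p = 0.117 with an estimated correlation). The chemokine gene Ccl2 was at 1.02 ± 1.5 CPM (SD, n = 3) against 51.2 ± 3.8 CPM (SD, n = 2), and H2-Ab1, for antigen presentation, at 1.34 ± 0.51 against 33.7 ± 26 CPM. The precursor list was lower with 0 of 8 genes called and the neuron list higher with 1 of 14 (camera adjusted p = 5.16e-05 and 9.25e-05, and adjusted p = 0.289 for both with an estimated correlation), with Stmn2 up by 2.26 ± 0.40. Abcc9 lost its call in 7 of 10 fits with a library left out, Flt1 in 5, Abcb1a and Stmn2 in 3, Lum in 2 and Ccl2 and H2-Ab1 in 1.

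No astrocyte-list gene was called between the GFP-positive groups, and 12 of 16 lay above 0 (camera adjusted p = 0.0693, and adjusted p = 0.704 with an estimated correlation). The list was called higher in some fits with a library left out. Among these were the fits without replicate 2 of the Lfng-GFP positive group (camera adjusted p = 0.0336) and without replicate 1 of the Lfng-GFP negative group (0.0444). The summed CPM of the list was 13030, 9221 and 13030 in the Lfng-GFP positive libraries. In the Aldh1l1-GFP positive group it was 3965 in replicate 1 and 17140 in replicate 2, so these replicates lay on either side of them. The groups therefore can be taken neither as equal nor as different in astrocyte genes. Lfng was higher by 2.74 ± 0.71 and did not pass (SE, adjusted p = 0.0742). The Notch list was called (camera adjusted p = 0.0332, and adjusted p = 0.6 with an estimated correlation) without a called member. Of the dorsal patterning genes, Zic1 was at 34.8 ± 23 CPM (SD, n = 3) against 3.91 ± 3.8 CPM (SD, n = 2), with a log2 fold change of 3.21 ± 0.81 (SE, adjusted p = 0.0668), and 3 of 6 passed when adjusted over the list alone. No ventral or Hox gene was called. The heat shock genes Hspa1b and Hspa1a were higher, by 3.17 ± 0.55 and 2.34 ± 0.48, and lost their calls in 2 and 7 of 10 fits with a library left out.

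The GFP-negative groups were compared as well, and the mouse line goes with the group here too. Microglia genes were lower in Lfng-GFP negative cells, with 7 of 14 called (camera adjusted p = 3.38e-31, and adjusted p = 0.199 with an estimated correlation) and 14 when adjusted over the list alone. Their summed CPM was 517, 227.3 and 269 in Lfng-GFP negative and 3871 and 3763 in Aldh1l1-GFP negative libraries. In the GFP-positive libraries it was 115.6, 226.7 and 1204 for Lfng and 2043 and 1902 for Aldh1l1. The gap thus lay in both gates and need not come from the sort. Tyrobp was at 21.2 ± 8.1 CPM (SD, n = 3) against 209 ± 20 CPM (SD, n = 2), and Itgam at 44.6 ± 24 against 657 ± 59 CPM. Clec7a had a log2 fold change of -6.11 ± 0.93 (SE, adjusted p = 0.0138). The endothelial genes Ly6c1 and Slco1a4 were higher, by 2.56 ± 0.53 and 2.04 ± 0.43 (camera adjusted p = 2.7e-14, and adjusted p = 0.199 with an estimated correlation), as were Hspa1b, by 3.57 ± 0.61, and Sox17, at 28.5 ± 5.8 against 2.21 ± 1.6 CPM. The largest rises were Brat1, at 13.2 ± 2.5 against 0.262 ± 0.37 CPM, and Iqce, at 29.5 ± 5.5 against 1.94 ± 2.0 CPM. They rest on pooled counts of 1 and 3 in Aldh1l1-GFP negative cells. Both lie near Lfng on chromosome 5, Iqce from 140661827 to 140702378 and Brat1 from 140705011 to 140719379. Why they differ between the lines was not tested. Without a called member, the mature oligodendrocyte and mural lists were called higher (camera adjusted p = 0.00273 and 0.00308), and the fibroblast, Hox 1 to 9, astrocyte and neuron lists lower (0.00308, 0.00767, 0.013 and 0.0292). The peripheral immune list was lower with 1 of 4 genes called (0.00767). With an estimated correlation their adjusted p was between 0.199 and 0.589. In all, 23 genes were higher and 64 lower. Without replicate 2 or 3 of the Lfng-GFP negative group, or either Aldh1l1-GFP negative library, both counts were 0.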

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

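All tests of explanations in this part were chosen after the results they bear on were seen, and intervals are 95% bootstrap intervals over the genes of a list, which leave out the spread between libraries. Gene lists were compared between the 2 sorts by the interaction contrast, and 13 lists passed with the preset correlation and none with an estimated one (adjusted p of 0.444 to 0.644). Positive values mean a larger log2 enrichment in the Lfng sort. The list medians were 0.80 for astrocyte, 1.65 for microglia, 1.82 for neuron, 2.46 for mural, 2.03 for peripheral immune, 0.474 for potassium, water and gap junction, 1.68 for reactive astrocyte and 0.613 for ribosomal protein genes. They were -0.884 for mature oligodendrocyte, -2.04 for oligodendrocyte precursor, -1.48 for fibroblast, -1.42 for cholesterol synthesis and -0.882 for immediate early and stress genes. The direction turned for the microglia list without replicate 3 of the Lfng-GFP positive group (adjusted p = 0.635), and for the potassium list without replicate 1 of the Aldh1l1-GFP positive group (adjusted p = 0.763).

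The Lfng sort called 869 genes, and the highest count among the other splits of the 6 libraries was 0. With 10 splits the share of splits as large, here 1 of 10, cannot go under 0.05.

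Replicate 1 of the Aldh1l1-GFP positive group lay below replicate 2 in astrocyte genes, by a median log2 ratio of -1.44 (interval -1.86 to -0.875), and above the negative libraries by 0.778 (interval 0.544 to 1.247). Other cell types moved apart between the replicates. Ependymal genes were higher in replicate 1 by 2.66 (interval 2.454 to 4.06), as were peripheral immune genes by 6.098, mural genes by 1.384, endothelial genes by 0.986 and the later neutrophil list by 6.571, whereas precursor genes were lower, by -2.224 (interval -2.67 to -1.16), and neuron genes by -1.714. The lower precursor genes go against more of every other cell type in replicate 1. Precursor genes lay 2.194 above the negative libraries in replicate 1 and 3.554 above them in replicate 2. They were thus higher on the positive side of the gate, and cannot decide against a lower share of GFP-positive cells in replicate 1. Immediate early genes lay 2.248 above the negative libraries in replicate 1 (interval 1.65 to 2.95) and 1.87 above them in replicate 2 (interval 1.48 to 2.52). This goes against a GFP-negative library under a positive label. These genes also differed between the 2 GFP-negative groups, by a list median of 1.318. They do not follow the gate alone, so such a label cannot be excluded. A mixture in which particular cell types entered that library may remain, and no biological explanation was tested, since both libraries carry the same labels. Replicates 1 and 2 also differed in Rn45s, at 4.07% and 35.6% of the counts, and in genes with a count, at 16277 and 12993. Whether these differences bear on their astrocyte genes was not tested.

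Endothelial and mural genes were higher in Lfng-GFP positive than in Aldh1l1-GFP positive cells. A difference between the lines or their preparations, shared by both gates, is consistent with the endothelial genes, whose difference of enrichments was 0.1657 (interval -0.112 to 0.256). It is argued against as the whole cause for mural genes, whose difference was 2.462 (interval 1.19 to 2.89). Mural cells within the Lfng-GFP gate are a candidate source, since mural genes were 1.318 higher in Lfng-GFP positive than negative cells (interval 0.848 to 2.04). By the same measure endothelial genes were 0.967 higher (interval 0.7999 to 1.154), so endothelial cells in that gate stay possible too. In the Aldh1l1 sort endothelial genes were 0.8023 higher in positive than negative cells (interval 0.4842 to 1.167). Line, preparation and reporter go together in this design, so reporter activity in mural or endothelial cells stays a hypothesis.

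Ribosomal protein genes were lower in the GFP-positive libraries of both sorts, by medians of -1.39 and -1.99. Their transcripts are short, with a median of 1076 bases against 3574 for other genes, taking the longest annotated transcript of each symbol. A trend on length and expression gave an expected -0.849 in the Lfng sort, and left -0.5716 (interval -0.641 to -0.46), so loss of short transcripts may account for a part. The longest transcript need not be the one expressed, so the remainder cannot decide whether this loss is the whole. A larger share of nuclear RNA cannot be told apart, since nuclear-retained RNAs had medians of 0.5052 (interval -0.954 to 1.49) in the Lfng sort and 1.836 (interval -3.06 to 3.12) in the Aldh1l1 sort. Of 9 members, 6 and 7 lay above 0. Their summed CPM was 14120 and 20890 in Aldh1l1-GFP positive against 2364 and 2043 in negative libraries, and 7639, 9657 and 10460 against 6337, 7905 and 4770 in the Lfng sort. These sums go with this explanation but are mostly counts of 1 abundant member. That list was written after the first results were seen. A cell type difference in ribosomal protein expression also stays open, untested.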

How the results depend on the processing

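The alternatives were planned before the data were examined, except the removal of Rn45s and the thinning to the smallest library, which were chosen after seeing the data and kept every count of calls, overlap and sorting check within 1.5 times or on its side of the threshold, as did RLE scaling. RLE moved the median of all genes by -0.107 on the log2 scale between the GFP-negative groups and by at most 0.0864 in size in the other comparisons. Counts are given as higher and lower genes, and the cause of their movement was not tested. With DESeq2 the Lfng sort had 803 higher genes, the Aldh1l1 sort 1083 and 1034, the GFP-positive groups 478 and 413, the GFP-negative groups 124 and 248, the difference of enrichments 68 and 53, and the overlap 265 higher genes. Without the filter on low counts there were 684 higher genes in the Lfng sort, 1031 in the Aldh1l1 sort, 442 and 559 between the GFP-positive groups, 271 and 282 between the GFP-negative groups, 80 and 109 for the difference and 266 higher genes in the overlap. With the compared groups alone, so with fewer libraries behind the spread, the counts were 923 and 875, 64 and 204, 0 and 1, and 397 and 571 for the 4 comparisons, and 37 and 163 for the overlap. With an estimated correlation 0 lists passed in each of the 5 comparisons. Leaving out single libraries, where a lone library left in an Aldh1l1-GFP group is assumed to vary like the other groups, gave ranges of 57 to 636 and 187 to 825 in the Lfng sort, 103 to 1174 and 235 to 1226 in the Aldh1l1 sort, 3 to 822 and 6 to 630 between the GFP-positive groups, 0 to 111 and 0 to 165 between the GFP-negative groups, 0 to 189 and 0 to 122 for the difference, and 29 to 251 and 135 to 461 for the overlap. The log2 fold change of Aldh1l1 in its sort ran from 0.498 to 2.43 and passed only at 2.15, without replicate 1 of the positive group. That of Lfng in its sort ran from 3.51 to 3.99 and kept its call in every setting. Lists past the threshold ranged from 7 to 16 in the Aldh1l1 sort and from 7 to 13 between the GFP-positive groups.

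Between the GFP-positive groups some directions turned when single libraries were left out. Cd44 and Thbs1, not called with all libraries, had fitted log2 fold changes from -3.31 to 7.96 and from -2.49 to 3.10, and both ends passed the threshold, the highest without replicate 1 and the lowest without replicate 2 of the Aldh1l1-GFP positive group. Of 4 lists not called with all libraries, the adjusted p ran from 0.00197 to 0.978 for mature oligodendrocyte, 0.025 to 0.978 for peripheral immune, 0.000205 to 0.991 for neurotransmitter and 0.000604 to 0.94 for ribosomal protein genes. They were called against their former direction without replicate 1 of the Lfng-GFP positive group for the oligodendrocyte list (adjusted p = 0.00197) and without replicate 2 of the Aldh1l1-GFP positive group for the others (adjusted p = 0.025, 0.000205 and 0.0218). In their former direction, the neurotransmitter list was called without replicate 1 of the Aldh1l1-GFP positive group (0.015), and the ribosomal protein list without that replicate (0.000604) and without replicate 3 of the Lfng-GFP positive group (0.00798). In the difference of enrichments, the adjusted p ran from 2.71e-06 to 0.635 for the microglia list and from 1.3e-06 to 0.763 for the potassium, water and gap junction list. The highest p of each went with a change of direction, without replicate 3 of the Lfng-GFP positive group and without replicate 1 of the Aldh1l1-GFP positive group. Over all genes the naming rule covers, single left-out libraries ended a call 499 times, added 139 and reversed 2, and for gene lists they ended 54, added 38 and reversed 6. The shallowest library, with 671033 counts, limits folds against the Aldh1l1-GFP negative group. No paired analysis was possible because the labels carry no numbers that pair libraries.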

Other observations

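The neutrophil list in this part was written after the first results were seen, and no explanation was tested for it. The summed CPM of its 11 genes was 806, 2001 and 194 in the Lfng-GFP positive libraries, and 66.2, 7.73 and 9.63 in the Lfng-GFP negative libraries. In the Aldh1l1-GFP positive group it was 1974 in replicate 1 and 44.4 in replicate 2, and in the negative group 77.4 and 58.7. S100a8 and S100a9, which the peripheral immune list also holds, were at 236 ± 210 and 335 ± 330 CPM in Lfng-GFP positive cells (SD, n = 3) and did not pass the test in the Lfng sort (adjusted p = 0.0532 and 0.0621).

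Between the GFP-negative groups, the cholesterol synthesis list was higher in Lfng-GFP negative cells with 0 of 21 genes called (camera adjusted p = 2.5e-06, and adjusted p = 0.519 with an estimated correlation). Insig1 was at 131 ± 50 CPM (SD, n = 3) against 37.5 ± 7.8 CPM (SD, n = 2) and was not called (adjusted p = 0.118). The immediate early and stress list was higher with 3 of 18 genes called (camera adjusted p = 2.84e-12, and adjusted p = 0.199 with an estimated correlation), with Fosb up by 2.05 ± 0.38 (SE, adjusted p = 0.0294). The reactive astrocyte list was called lower with 0 of 22 genes called and 7 above 0 (camera adjusted p = 0.00066, and adjusted p = 0.505 with an estimated correlation), and C3, a complement gene, was at 11.5 ± 7.2 against 127 ± 32 CPM without being called (adjusted p = 0.0951). The ribosomal protein list was lower (camera adjusted p = 1.22e-13, and adjusted p = 0.519 with an estimated correlation) with a median of -0.54. Rpl29 and Rplp1 were the 2 of its 74 genes called, with log2 fold changes of -2.69 ± 0.43 and -1.99 ± 0.40.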
